A study of Arabidopsis thaliana with 32 samples.

How the data were processed

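Whole roots of 32 samples were sequenced by the authors, 4 in each of 8 groups given by genotype (WS or sku5), environment (spaceflight or ground control) and age (4 d or 8 d). Seedlings grew on upright plates in the Veggie unit at 100 to 135 µmol of light per m2 and s, and the ground control ran with a 48-h delay in a chamber that copied the station's temperature, carbon dioxide and lighting. Libraries were made by the authors from 10 ng of total RNA with SMART-Seq v4 and Nextera kits. The submitters' notes name Trimmomatic 0.36, FastQC 0.11.2, STAR 2.5.1b, Picard, Cufflinks and Cuffdiff, and neither their roles nor the genome build are given in the sources used here.

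The values are those of 11 tables that the authors deposited, each of which compares a pair of groups with Cuffdiff. Per the file headers the authors give 1 FPKM value for each group and locus. Their fold change is given per the file headers on the log2 scale, and is infinite where a value is 0. The authors' test statistic is a signed score of that fold change. Each locus also has the p-value and the q-value that the authors deposited, and the p-values come in steps of 5e-05. Every locus in these tables is marked significant by the authors, at a q-value under 0.05, so the loci that were tested and not called, and their number, are not known. No table holds values per library. Depth per sample is therefore unknown. The precision of a fold change is known only through the authors' log2 fold change divided by their test statistic, called its standard error here. For some loci the deposited p is far below what a normal distribution gives for that score. AGL42 (AT5G62165), for spaceflight in WS at 4 d, has a log2 fold change of -2.20, a standard error of 1.25 and a Cuffdiff p of 5e-05. The standard error is therefore a rough scale. Its median in a comparison lies between 0.279 and 0.532 on the log2 scale. The values of a group differ between tables by a constant factor of up to 10.8%, with a standard deviation of the log2 ratio of at most 0.00245 over the 20 pairs of tables that share a group, so values set across tables are on slightly different scales.

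Directions were turned so that spaceflight stands over ground, 8 d over 4 d and sku5 over WS. The tables hold 10961 entries for 4882 loci, of which 4458 carry a single gene name, 378 merge several genes and 46 have no name. Of the single genes, 4446 were found by identifier in the reference annotation of 38094 genes, which gave products and transcript lengths. The authors' calls were used as deposited. A fit of separate libraries, planned in case the tables held them, could not be made, and no count over other splits of the samples, test for outlying samples or repeat without a replicate was possible from group values.

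These choices were made before the data were examined: the comparisons, tests, gene lists, named genes and alternatives, except where stated. Overlaps of calls between comparisons were tested in 10 pairs with 2-sided Fisher's exact tests of loci higher in both, lower in both, and of sign among loci called in both, 30 tests in all, of which 26 passed. Their background, and that of the list tests, is the 4882 loci listed in any table, and not all genes tested by the authors. List members are counted as loci, so a gene given more than a single locus counts at each, and a merged locus counts once. The 27 gene lists hold 591 genes named by identifier, and the genes of the chloroplast and mitochondrial genomes. With the number of genes fixed, they cover the SKU5 family (19), root skewing (12), expansins and xyloglucan enzymes (41), root hairs (23), class III peroxidases (29), heat shock (28), photosynthesis (31), light signalling (13), the clock (16), flavonoids (14), auxin (41), cytokinin (18), jasmonate (22), defence (25), touch and calcium (27), hypoxia (21), cold and dehydration (29), seed reserves (18), oxidative stress (25), iron (21), phosphate (18), nitrate and ammonium (19), the cell cycle (20), the root stem cell niche (10), secondary walls (30), suberin and the Casparian strip (21), and organelle genomes. WVD2 was left out because its listed identifier belongs to another gene in the reference. Each list was tested in each comparison with a 2-sided Fisher's exact test of called against other background loci, 297 tests, of which 13 passed. Where at least 3 members were called, their direction was tested against the other called loci with the same exact test, 114 tests, of which 0 passed, with 23 at an unadjusted p under 0.05. The spaceflight effects of the genotypes, and the age effects of the environments, were compared for loci called in both tables, as the difference of the log2 fold changes over its standard error against a normal distribution. That is an approximation, as no exact test can be made from values per group, so differences and standard errors are given for it and no p. The deposited p-values do not always follow the authors' score as a normal one, so the numbers of loci passing are approximate too. Loci listed at 0 have no standard error and were not tested. All p-values were adjusted by Benjamini and Hochberg's method within each kind of test, and an adjusted p under 0.05 passed.

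Genes were named by a rule: SKU5, the 6 largest rises and 6 largest falls in each comparison among loci with at least 5 FPKM in the higher group and a value above 0 in the other, up to 4 members of each list that passed or, where none did, of the 4 lists with most called members, and up to 8 loci called in the same direction in the most spaceflight comparisons. A gene that the rule names is not reported here. Genes named beyond this rule are those whose difference of effects passed, and those of patterns chosen after their values were seen.

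The alternatives tried were a q under 0.01, an absolute log2 fold change of at least 1 or 2, floors of 1 and 5 FPKM in the higher group, loci listed at 0 left out, the log2 of the values plus 1, rises or falls alone, and all reference genes as background. After the data were seen, loci of a single named gene were also taken alone, and the loci listed for genotype on the ground at 4 d were left out of the sku5 spaceflight comparison at 4 d, and SKU5 was left out of its own list for genotype in spaceflight. The tests were also run on simulated data of the size of the sku5 spaceflight comparison at 4 d, 4882 loci with 1007 called, in 200 rounds. Planted lists were recovered in 100% of rounds and 0.346% of other lists passed. A planted direction was recovered in 100% of rounds and 0.0192% of other lists passed. Each planted list had more called members than any real list, all in a single direction, and p-values were adjusted within a single comparison. That recovery therefore cannot show that real lists with few called members would have passed. Independent draws gave an overlap p under 0.05 in 4% of tests, and planted overlaps were found in 100% of rounds. All draws were taken from the 4882 loci, so they could not show any effect of that choice of background. Planted differences of effects of 5 standard errors were recovered for 98.8% of loci, and 4.97% of the loci passing were false. That simulation drew its noise from the same standard errors that the test uses, without choosing loci called in both tables. It checks the computation alone, and cannot show that the standard errors or the share of false loci hold for these data. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.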

Results

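RNA was measured in whole roots of Arabidopsis thaliana seedlings grown on plates of solid medium in the Veggie unit of the International Space Station or in a ground unit of the same hardware. The plants were the wild type WS (Wassilewskija) and the sku5 mutant of SKU5, a gene that affects the direction of root growth. Roots were fixed at 4 d or 8 d, which gave 8 groups of 4 samples each. A replicate pooled 5 to 8 roots at 4 d and 2 to 3 roots at 8 d. The authors' deposited tables cover 11 comparisons, give a single FPKM value for each group, and list only the loci that their Cuffdiff test marked significant. The depth of each library is not given in the sources used here, and no spread between replicates can be computed from group values. The comparison of sku5 with WS in spaceflight at 4 d was not analysed here. A count below is a count of loci that the authors marked significant, at a q-value under 0.05, and the first-named group is set over the second. Gene lists, apart from that of organelle genomes, were fixed at 10 to 41 genes each, of which 2 to 20 loci are listed in any table, and a count such as 3 of 9 is over the listed loci alone. No list passed its test of direction among all called loci in any comparison.

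**Figure D1:**
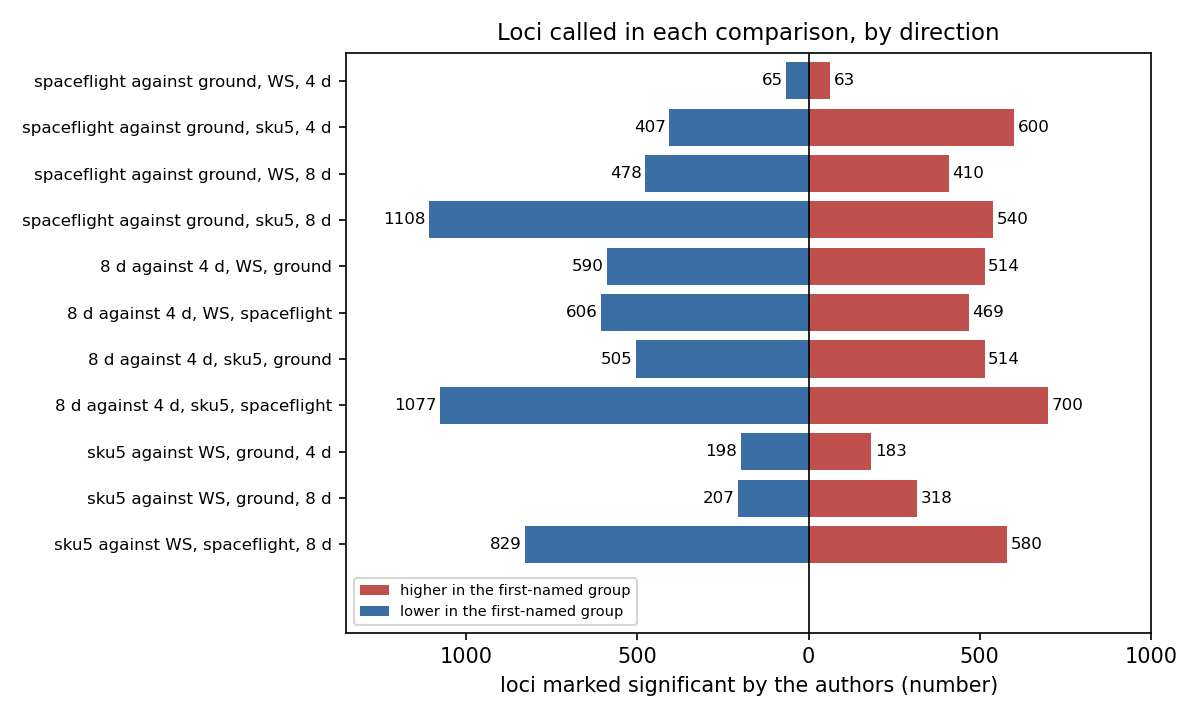
Bars give the number of loci that the authors marked significant in each of the 11 comparisons, to the right for loci higher in the first-named group and to the left for loci lower. The smallest comparison holds 63 higher and 65 lower loci, and the most falls, 1108, stand in sku5 roots in spaceflight at 8 d.

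The mutated gene itself was lower in the sku5 samples wherever the genotypes were compared. SKU5 (AT4G12420), on chromosome 4 at 7143426 to 7147294 in the authors' coordinates (build not given in the sources used here), encodes a membrane-anchored protein related to multicopper oxidases. At 4 d on the ground it stood at 10.4 against 38.9 FPKM in sku5 and WS in the authors' deposited table, 3.72-fold lower in the mutant (q = 0.00558). At 8 d on the ground the authors' deposited table gave 24 against 78.6 FPKM, 3.34-fold lower (q = 0.00381). In spaceflight at 8 d the values in the authors' deposited table were 14.2 against 61.9 FPKM, 4.35-fold lower (q = 0.00182). SKU5 rose between 4 d and 8 d on the ground, 1.86-fold in WS (q = 0.00217) in the authors' deposited table, and 2.06-fold in sku5 (q = 0.00209). At 8 d it was lower in spaceflight in both genotypes in the authors' deposited table, at 61.3 against 78.6 FPKM in WS (q = 0.00797) and 14.2 against 23.8 FPKM in sku5 (q = 0.00136). It is not listed for spaceflight at 4 d, or for age in spaceflight, in either genotype.

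Spaceflight against ground in 4-d WS roots asks how young wild-type roots differed on orbit. The photosynthesis and seed reserve lists passed, with all called members higher in spaceflight, as was the touch-induced calmodulin-like gene TCH3. In root samples the photosynthesis list also marks green shoot tissue, and the seed reserve list residual seed material. Genes for the small subunit of Rubisco, the carbon-fixing enzyme, stood in the authors' deposited table at 65.8 against 21.6 FPKM for RBCS3B (AT5G38410), 40.7 against 15.0 FPKM for RBCS1B (AT5G38430) and 34.3 against 14.8 FPKM for RBCS2B (AT5G38420). Rubisco activase, RCA (AT2G39730), stood there at 40.5 against 18.1 FPKM, and q in the authors' deposited table ran from 0.0113 to 0.0271 over these genes. Of the 10 photosynthesis genes listed in any table, 5 were called here and all 5 were higher (Fisher's exact test, adjusted p = 0.000772). Seed reserve genes gave 3 of 9, all higher (Fisher adjusted p = 0.0391): the embryo protein gene GEA6 (AT2G40170) at 452 against 191 FPKM, the oil body gene OLEO4 (AT3G27660) at 61.4 against 24.5 FPKM and MLS (AT5G03860), malate synthase of the glyoxylate cycle, at 25.3 against 13.2 FPKM in the authors' deposited table.

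Largest among the rises in the authors' deposited table were those of the microRNA gene MIR158b (AT1G55591), 12.6-fold (q = 0.0113), TCH3 (AT2G41100), 5.58-fold to 52.6 FPKM (q = 0.0113), and the ribonuclease gene RNS1 (AT2G02990), 5.33-fold (q = 0.0328). GSTF3 (AT2G02930), a glutathione transferase, rose 4.98-fold, GLYI7 (AT1G80160), of the glyoxalase I family, 4.81-fold, and the glycine-rich protein gene AT2G05510 4.45-fold in the authors' deposited table. The largest falls there were those of the MADS-box gene AGL42 (AT5G62165), from 7.36 to 1.60 FPKM in the authors' deposited table (q = 0.0113), and of the locus that merges MIR398a and PAP9 (AT2G03445, AT2G03450), 3.57-fold lower. LAF1 (AT4G25560), a MYB transcription factor of light signalling, fell 3.25-fold and MTPA2 (AT3G58810), a metal transporter, 3.12-fold in the authors' deposited table. The defensin-like gene AT5G33355 fell from 767 to 250.5 FPKM and AT1G30990 from 123 to 42.6 FPKM in the authors' deposited table.

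Of the 128 loci called, 63 were higher and 65 lower. At least 2-fold changes were 52 higher and 29 lower, so the even split did not hold there, and 5 of the rises are of loci listed at 0 on the ground. The smallest q is 0.0113, so no locus is left at a q under 0.01, and at a change of at least 2-fold the seed reserve call ended (Fisher adjusted p = 0.623).

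In 4-d sku5 roots the same comparison asks how the mutant differed on orbit. The suberin and Casparian strip list passed, with all called members lower in spaceflight, and genes of the maturing seed were among the largest rises. GEA6 (AT2G40170) stood at 1205 against 2.06 FPKM (q = 0.00207), the late embryogenesis gene AT3G17520 at 383 against 0.862 FPKM and the vicilin-like storage gene PAP85 (AT3G22640) at 363 against 0.822 FPKM in the authors' deposited table. The other large rises in the authors' deposited table were AT1G54870 at 863 against 0.524 FPKM, AT1G68250 at 6018 against 8.75 FPKM and AT1G03106 at 1301 against 4.66 FPKM. For 39 of the rises the locus is listed at 0 on the ground, and no fold is given. Of the 9 seed reserve genes listed in any table, 4 were called and all were higher. The list did not pass its test in this comparison (Fisher adjusted p = 0.507).

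The suberin and Casparian strip list, of genes for barriers in the walls of inner root cells, had 7 of 9 members called, all lower (Fisher adjusted p = 0.0203). The suberin exporter gene ABCG6 (AT5G13580) fell from 6.97 to 1.08 FPKM (q = 0.0458) and the fatty acid hydroxylase gene CYP86B1 (AT5G23190) from 6.24 to 1.41 FPKM (q = 0.00917) in the authors' deposited table. The merged locus of the fatty acid reductases FAR5 and FAR8 (AT3G44550, AT3G44560) fell 2.80-fold and the acyltransferase gene GPAT5 (AT3G11430) 2.68-fold in the authors' deposited table. Class III peroxidases, which cross-link cell wall phenolics, gave 7 of 17 called, all lower (Fisher adjusted p = 0.392), and heat shock genes 6 of 12, all higher (0.229), and neither list passed. Tested for direction against the rest of this table, the suberin and the peroxidase lists each had an adjusted p of 0.0649 and the heat shock list 0.249. Largest among the falls in the authors' deposited table were those of AIR1 (AT4G12550), a gene induced by auxin in root cultures, 13.2-fold (q = 0.0438) at this locus and 2.51-fold at the more abundant locus that merges it with AT4G12545, ABCG6, 6.44-fold, and UGT84A1 (AT4G15480), a glucosyltransferase gene, 6.39-fold. AT2G36295 fell 6.24-fold, AT3G59930 6.09-fold to 280.1 FPKM and AT1G03700 5.84-fold in the authors' deposited table.

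Of the 1007 loci called, 600 were higher and 407 lower, and at least 2-fold 439 and 195. The suberin call ended at a q under 0.01 (Fisher adjusted p = 0.419) and at a change of at least 2-fold (Fisher adjusted p = 0.393), where its direction test gave an adjusted p of 0.0177 with 6 members lower and 0 higher.

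**Figure D2:**
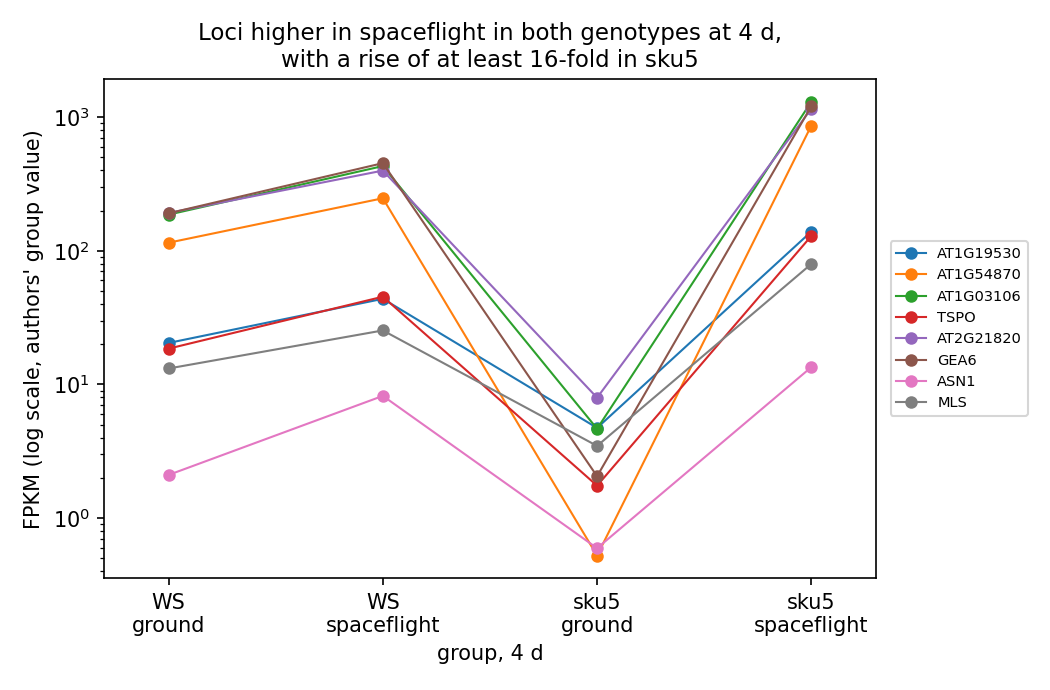
Points give the authors' FPKM at 4 d, on a log axis, of the 8 loci that rose in spaceflight in both genotypes and by at least 4 on the log2 scale in sku5, and lines join the values of the same locus. Each locus is lowest in sku5 on the ground and highest in sku5 in spaceflight, such as GEA6 at 2.06 and 1205 FPKM, and the values of the 2 genotypes come from separately scaled tables.

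At 8 d, spaceflight against ground in WS roots asks about older wild-type roots. No gene list passed its test here, in number or in direction, so the 4 lists with most called members are described. Of the 20 auxin genes listed in any table, 9 were called, 6 higher and 3 lower (Fisher adjusted p = 0.085). The auxin repressor gene IAA7 (AT3G23050) rose to 64.3 FPKM from 36.8 (q = 0.00259) and ARF19 (AT1G19220), for an auxin response factor, to 3.51 FPKM from 2.17 in the authors' deposited table. LBD29 (AT3G58190), a transcription factor of lateral root formation, fell to 3.25 FPKM from 7.62 (q = 0.0474) in the authors' deposited table. Among expansins and xyloglucan enzymes, which loosen the cell wall, 6 of 18 were called, 1 higher and 5 lower: in the authors' deposited table XTH9 (AT4G03210) stood at 122 against 260.0 FPKM, EXPA15 (AT2G03090) at 206 against 303 FPKM, EXPA6 (AT2G28950) at 57.7 against 86.0 FPKM and, higher, EXLB1 (AT4G17030) at 22.2 against 12.3 FPKM. Cold and dehydration genes gave 4 of 17, all lower: KIN1 (AT5G15960) at 37.6 against 121 FPKM, KIN2 (AT5G15970) at 499 against 1052 FPKM, COR413-PM1 (AT2G15970) at 562 against 784 FPKM and the merged locus of AT3G50860 and the dehydrin LTI30 (AT3G50970) at 75.7 against 153 FPKM in the authors' deposited table. Class III peroxidases gave 5 of 17, 1 higher and 4 lower: in the authors' deposited table AT5G19890 rose 2.72-fold, while the merged locus PRXCA and PRXCB (AT3G49110, AT3G49120) fell 1.94-fold, AT1G44970 1.55-fold and AT4G11290 1.36-fold.

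Among rises in the authors' deposited table the largest were those of AT5G66840, a gene for a SAP domain protein, 8.33-fold, AT1G12805, 6.46-fold, and a locus of the mitochondrial genome without a gene name, from 1.80 to 10.2 FPKM. AT2G14247 rose 5.64-fold in the authors' deposited table. FTM1 (AT1G43800), a stearoyl desaturase gene also listed under hypoxia, rose from 4.19 to 22.5 FPKM (q = 0.00259) and the peroxidase gene AT1G49570 5.47-fold in the authors' deposited table. Among falls in the authors' deposited table the largest were those of the merged locus LPP2 and AT1G15090 (AT1G15080), 15.1-fold (q = 0.00797), MIR158b (AT1G55591), 8.89-fold, and the merged locus UGT71C3 and AT1G07270 (AT1G07260), 4.84-fold. The receptor kinase gene AT4G22730 fell 4.36-fold, AT3G21805 4.04-fold and AT2G33850 3.40-fold in the authors' deposited table. The LPP2 locus had a log2 fold change of -3.92 with a standard error of 2.79. This locus and MIR158b are also among the largest changes for age in WS on the ground and genotype on the ground at 8 d. Those comparisons share the WS ground libraries of 8 d with this one, so the changes are not separate results.

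Of the 888 loci called, 410 were higher and 478 lower, with a median standard error of 0.30 on the log2 scale. Of the 143 that differed at least 2-fold, 88 were higher and 55 lower, so the larger side turned. No locus is listed at 0 in this comparison.

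In 8-d sku5 roots seed storage genes were among the largest rises in spaceflight, and no gene list passed its test in number or, among all called loci, in direction. Cruciferin seed storage genes stood in the authors' deposited table at 113 against 1.39 FPKM for CRU3 (AT4G28520, q = 0.0435) and 84.4 against 0.708 FPKM for CRA1 (AT5G44120, q = 0.0435). SESA2 (AT4G27150), a seed albumin, stood at 13.9 FPKM in spaceflight and OLEO4 (AT3G27660) at 5.80 FPKM in the authors' deposited table, and both are listed at 0 on the ground. In all, 6 of the 9 seed reserve genes were called and 6 were higher, with a direction adjusted p of 0.0649 against the rest of this table, and of 0.0064 at a change of at least 2-fold. The other largest rises in the authors' deposited table were GEA6 (AT2G40170) at 38.5 against 1.84 FPKM, the late embryogenesis gene AT3G15670 at 9.10 against 0.715 FPKM, AT1G54870 at 35.6 against 0.625 FPKM and AT1G03106 at 79.3 against 3.03 FPKM.

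Cold and dehydration genes gave 7 of 17, all lower: in the authors' deposited table KIN1 (AT5G15960) stood at 33.2 against 92.1 FPKM, KIN2 (AT5G15970) at 344 against 769 FPKM, ERD10 (AT1G20450) at 70.0 against 129.9 FPKM and the AT3G50860 and LTI30 locus at 70.4 against 152 FPKM. Of 10 hypoxia genes, 5 were called and all were lower, in a table where 67.2% of all called loci were lower. Auxin genes gave 5 of 20, 1 higher and 4 lower: in the authors' deposited table the efflux carrier gene EIR1 (AT5G57090) rose 1.76-fold, while IAA2 (AT3G23030) fell 2.63-fold, IAA28 (AT5G25890) 1.51-fold and IAA14 (AT4G14550) 1.47-fold. Class III peroxidases gave 9 of 17, 2 higher and 7 lower, among them PRXCA (AT3G49110) at 18.0 against 47.5 FPKM, RHS19 (AT5G67400) at 72.7 against 119 FPKM, AT4G26010 at 69.3 against 105 FPKM and AT1G44970 at 12.6 against 18.6 FPKM in the authors' deposited table. The largest falls in the authors' deposited table were those of MIR160b (AT4G17788), a microRNA gene aimed at auxin response factors, 18-fold (q = 0.00136), AT1G12805, 12.8-fold, and the thioredoxin gene TH7 (AT1G59730), 10.7-fold. The glycine-rich protein gene GRP-3 (AT2G05520) fell 6.21-fold, AZI1 (AT4G12470), a lipid transfer protein gene of defence priming, 5.27-fold and AT1G73490, for an RNA-binding protein, 5.20-fold in the authors' deposited table.

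Of the 1648 loci called, 540 were higher and 1108 lower, and at least 2-fold 56 and 187. The loci that were lower had shorter transcripts, with a median length of 1009 nucleotides in the reference annotation against 2286 for those that were higher.

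Calls for spaceflight were set against each other across genotypes and ages, over libraries that these comparisons do not share. At 4 d, 59 loci were called in both genotypes and 57 moved the same way. The 25 higher in both compare with 7.74 for independent lists (Fisher adjusted p = 3.59e-08) and the 32 lower in both with 5.42 (Fisher adjusted p = 4.29e-18). At 8 d, 312 loci were called in both genotypes, 277 in the same direction. The 225 lower in both compare with 108 for independent lists (Fisher adjusted p = 3.69e-35), and the 52 higher in both with 45.4 (Fisher adjusted p = 0.294). In both tables of 8 d the lower loci had shorter transcripts than the higher, by 0.89 in WS and 1.18 in sku5 in median log2 length, a lean that the overlap test leaves out of account. Between 4 d and 8 d, WS shared 38 calls, against 23.3 for independent lists, with 34 in the same direction. In sku5 265 were shared, against 340 for independent lists, with 247 in the same direction. The background holds only loci called in some comparison, which sets the expected numbers high. A shared number near or below the expected 1 therefore does not show a lack of sharing. In both genotypes the ages shared more falls than independent lists would: 25 against 6.36 in WS (Fisher adjusted p = 7.53e-10) and 179 against 92.4 in sku5 (Fisher adjusted p = 4.35e-23). Rises shared between ages were 9 against 5.29 in WS (Fisher adjusted p = 0.116) and 68 against 66.4 in sku5 (Fisher adjusted p = 0.835). Changes in the same direction in all 4 spaceflight comparisons were found for 13 loci, and 8 of them are named here. HSP90.1 (AT5G52640), a heat-inducible chaperone gene, rose 1.86-fold in WS at 4 d, 3.98-fold in sku5 at 4 d, 1.83-fold in WS at 8 d and 1.87-fold in sku5 at 8 d in the authors' deposited table. The glycine-rich protein gene AT2G05510 was also higher in all 4, from 7.89 to 49.1 FPKM in sku5 at 4 d in the authors' deposited table. The other 6 were lower in all 4. In sku5 at 4 d the authors' deposited table gave 708 against 1372 FPKM for the thioredoxin gene TRX5 (AT1G45145), 78.6 against 198 FPKM for HIPP25 (AT4G35060), of the heavy-metal-binding family, and 287 against 647 FPKM for the lipid transfer gene AT3G22600. The merged lipid transfer locus AT4G12545 and AIR1 stood at 930.0 against 2335 FPKM, the dirigent-like gene AT2G39430 at 24.9 against 44.4 FPKM and AT2G19970, of the cysteine-rich secretory family, at 33.0 against 54.0 FPKM in the authors' deposited table.

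**Figure D3:**
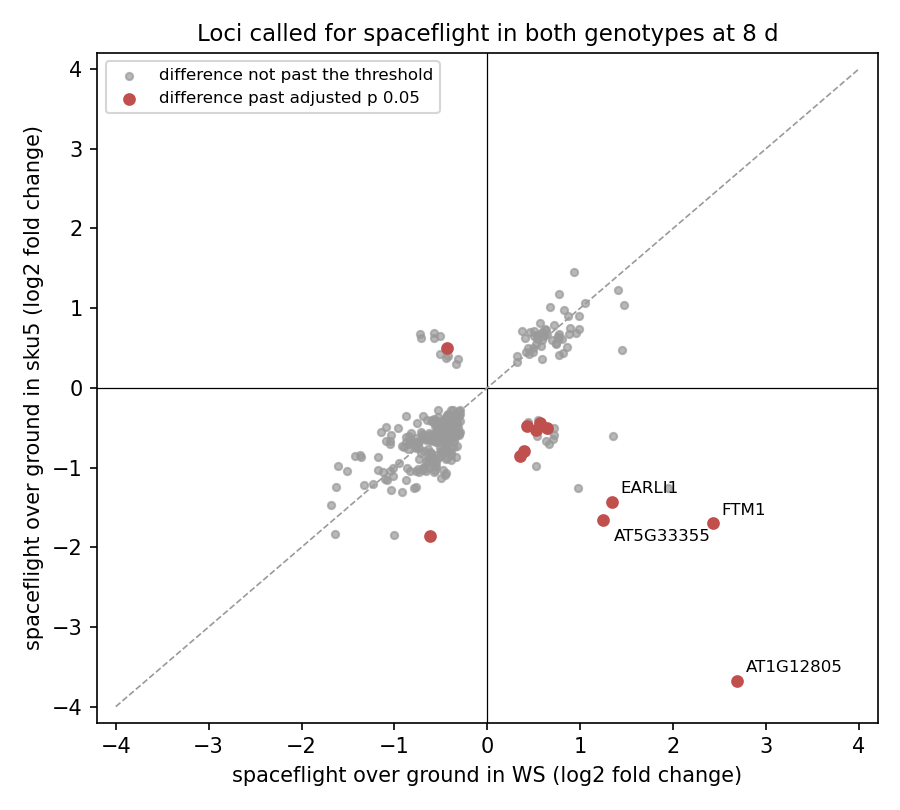
Points give the 312 loci called for spaceflight in both genotypes at 8 d, with the authors' log2 fold change in WS on the horizontal axis and in sku5 on the vertical axis. Most points, 277, lie on the same side of 0 on both axes, and the 12 whose difference passed the test are in red, FTM1 at 2.43 in WS and -1.70 in sku5 among them.

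The spaceflight effects of the genotypes were also tested against each other for the loci called in both. Differences and standard errors were computed here from the fold changes and test statistics of the authors' deposited tables. Those standard errors are rough, so the numbers of loci that differed are approximate. At 4 d, 11 of 59 loci differed, and 9 of the 11 moved the same way in both genotypes. GEA6 (AT2G40170) rose by 9.20 on the log2 scale in sku5 and by 1.25 in WS (difference 7.95, standard error 1.15). RNS1 (AT2G02990) rose by 2.41 in WS and fell by 1.92 in sku5 (difference -4.33, standard error 1.32). At 8 d, 12 of 312 loci differed and 11 of them moved in opposite directions. The median absolute log2 effect of the 312 was 0.64 in sku5 and 0.56 in WS, so a pair of the same sign could seldom differ enough to pass. The share of opposite directions thus follows in part from the choice of loci, and loci called in a single genotype were not tested. FTM1 (AT1G43800) rose by 2.43 in WS and fell by 1.70 in sku5 (difference -4.12, standard error 0.68), and AT1G12805 rose by 2.69 in WS and fell by 3.67 in sku5 (difference -6.37, standard error 1.43). EARLI1 (AT4G12480), a lipid transfer protein gene, rose by 1.34 in WS and fell by 1.43 in sku5 (difference -2.77, standard error 0.75).

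Age, 8 d against 4 d, was compared within each genotype and environment to ask how roots changed as they grew. In WS on the ground, the phosphate starvation and hypoxia lists passed, the former with falls and the latter with more rises than falls among called members. Of 11 phosphate genes, 8 were called and all were lower at 8 d (Fisher adjusted p = 0.0241, and 0.119 for direction). This list was also all lower in sku5 on the ground, 7 of 11, and in WS in spaceflight, 5 of 11, without passing (Fisher adjusted p = 0.0536 and 0.413), and in sku5 in spaceflight it gave 1 higher and 5 lower. The sensor gene SPX1 (AT5G20150) fell to 26.5 FPKM from 87.7, the transporter gene PHT1;4 (AT2G38940) to 8.62 FPKM from 28.3, SRG3 (AT3G02040) to 16.1 FPKM from 49.6 and PHO1;H1 (AT1G68740) to 5.31 FPKM from 15.4, each with q = 0.00217 in the authors' deposited table. Of 10 hypoxia genes, 7 were called, 6 higher and 1 lower (Fisher adjusted p = 0.0455, and 0.235 for direction). Photosynthesis genes gave 5 of 10 and seed reserve genes 5 of 9, all lower, without passing (Fisher adjusted p = 0.359 and 0.271), and these lists mark shoot tissue and seed material. FTM1 (AT1G43800) rose 3.37-fold, the plant cysteine oxidase gene PCO1 (AT5G15120) 3.27-fold and the ethylene-forming ACO1 (AT2G19590) 2.48-fold, while LBD40 (AT1G67100) fell 2.86-fold in the authors' deposited table.

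The largest rises in the authors' deposited table were those of the merged locus LPP2 and AT1G15090 (AT1G15080), 18.0-fold, the thioredoxin gene TH8 (AT1G69880), 17.3-fold to 108 FPKM, and MIR158b (AT1G55591), 16.5-fold. MIR160b (AT4G17788) rose 10.3-fold, AT5G44400, for a berberine-bridge-like enzyme, to 32.1 FPKM from 3.17 and the oxygenase gene AT1G52800 9.82-fold in the authors' deposited table. Largest among the falls in the authors' deposited table were those of AT2G21820, from 208 to 4.42 FPKM, AT1G03106, from 202 to 4.78 FPKM, and the small heat shock gene HSP17.4 (AT3G46230), 25.8-fold. RBCS2B (AT5G38420) fell 19.9-fold, GLYI8 (AT2G28420) 22-fold and the merged locus AT3G16117 and AT3G16120 24.1-fold in the authors' deposited table.

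Of the 1104 loci called, 514 were higher and 590 lower, at least 2-fold 202 and 306, and 34 are listed at 0 at either age. At a q under 0.01 the phosphate call ended (Fisher adjusted p = 0.149), as did the hypoxia call (Fisher adjusted p = 0.319), and at a change of at least 2-fold they gave 0.526 and 0.136.

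In WS in spaceflight, called photosynthesis genes, which also mark green shoot tissue, all fell with age, and 3 MADS-box genes were among the largest rises. Of 10 photosynthesis genes, 9 were called and all were lower at 8 d (Fisher adjusted p = 0.00141). The fall was not seen here alone: 5 were called in WS on the ground, 5 in sku5 on the ground and 6 in sku5 in spaceflight, all lower, without passing (Fisher adjusted p = 0.359, 0.295 and 0.784). RBCS3B (AT5G38410) fell to 2.60 FPKM from 67.5, RBCS1B (AT5G38430) to 2.23 FPKM from 41.8, RBCS2B (AT5G38420) to 1.94 FPKM from 35.2 and RCA (AT2G39730) to 6.62 FPKM from 41.6, each with q = 0.00218 in the authors' deposited table. The MADS-box genes AGL19 (AT4G22950), AGL42 (AT5G62165) and AGL14 (AT4G11880) rose 36.0-fold, 24-fold and 11.5-fold in the authors' deposited table. The germin-like gene GLP6 (AT5G39100) rose 22.6-fold, AT5G44400 21.9-fold and FTM1 (AT1G43800) 18-fold to 20.6 FPKM in the authors' deposited table. Among falls in the authors' deposited table the largest were those of the merged small heat shock locus HSP17.6II and HSP17.6A (AT5G12020, AT5G12030), from 306 to 0.583 FPKM (q = 0.0378), AT1G03106, 127-fold, and AT2G21820, 123-fold. The dehydrin gene XERO1 (AT3G50980) fell 115-fold, AT3G05260 77.2-fold and HSP17.4 (AT3G46230) 56.3-fold in the authors' deposited table.

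Of the 1075 loci called, 469 were higher and 606 lower, at least 2-fold 196 and 244, and 28 are listed at 0 at either age.

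In sku5 on the ground, 4 lists passed for age: hypoxia, expansins and xyloglucan enzymes, iron and oxidative stress. Hypoxia genes gave 8 of 10 called, 7 higher and 1 lower (Fisher adjusted p = 0.0105, and 0.235 for direction). FTM1 (AT1G43800) rose to 15.2 FPKM from 0.60, PCO1 (AT5G15120) to 16.7 FPKM from 3.91, the hemoglobin gene HB1 (AT2G16060) to 166 FPKM from 39.9 and LBD41 (AT3G02550) to 17.5 FPKM from 4.70, each with q = 0.00209 in the authors' deposited table. Expansins and xyloglucan enzymes gave 10 of 18, 7 higher and 3 lower (Fisher adjusted p = 0.0391, and 0.496 for direction). Among them EXPA6 (AT2G28950) rose 3.41-fold, EXPA4 (AT2G39700) 3.39-fold, EXPA15 (AT2G03090) 2.97-fold and EXPB3 (AT4G28250) 2.38-fold in the authors' deposited table. Iron genes gave 7 of 9, all lower (Fisher adjusted p = 0.0203, and 0.117 for direction). Falls of iron genes were not seen here alone: 6 of 9 were called in WS on the ground and 7 in sku5 in spaceflight, all lower, without passing (Fisher adjusted p = 0.0871 and 0.163). In WS in spaceflight only 1 of 9 was called, also lower. The merged locus of AT4G19650 and the iron transporter IRT1 (AT4G19690) fell to 56.0 FPKM from 345 and the merged regulators bHLH38 and bHLH39 (AT3G56970, AT3G56980) to 32.4 FPKM from 137 in the authors' deposited table. CYP82C4 (AT4G31940), a gene of iron-deficient roots, fell 4.51-fold and NAS4 (AT1G56430), a nicotianamine synthase, 3.3-fold in the authors' deposited table. Oxidative stress genes gave 8 of 12, 5 higher and 3 lower (Fisher adjusted p = 0.0288): in the authors' deposited table the superoxide dismutases CSD1 (AT1G08830) and CSD2 (AT2G28190) rose 2.1-fold and 2.0-fold, GSTU4 (AT2G29460) rose 2.22-fold and the alternative oxidase AOX1A (AT3G22370) fell 2.38-fold.

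Largest among the rises in the authors' deposited table were those of FTM1, 25.3-fold, TH8 (AT1G69880), 25.3-fold, and the lipid transfer gene LTP5 (AT3G51600), 15.5-fold. AT4G14060 rose 15.4-fold, the peroxidase gene AT5G19890 15.3-fold and the methyltransferase gene AT1G77520 13.9-fold in the authors' deposited table. The largest falls in the authors' deposited table were those of the defensin-like genes AT1G34047, 30.6-fold, and AT5G33355, 17.1-fold to 82.0 FPKM, and of RBCS3B (AT5G38410), from 21.0 to 1.33 FPKM. LCR85 (AT4G22210), also defensin-like, fell 14.4-fold, GRP-3 (AT2G05520) 12.2-fold and AT1G78450, for a heme-binding protein, 10.7-fold in the authors' deposited table.

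Of the 1019 loci called, 514 were higher and 505 lower, and at least 2-fold 259 and 227. At a change of at least 2-fold the expansin, iron and oxidative stress calls ended (Fisher adjusted p = 0.408, 0.136 and 1.0), and the oxidative stress call also ended at a q under 0.01 (Fisher adjusted p = 0.149).

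In sku5 in spaceflight, called seed reserve genes, which mark residual seed material, all fell with age. Of the 9 seed reserve genes, 8 were called and all were lower at 8 d (Fisher adjusted p = 0.0455), against the same 4-d libraries that stand in the spaceflight comparison. In WS 5 of 9 were called on the ground and 5 in spaceflight, all lower, without passing. In sku5 on the ground only 1 of 9 was called, also lower. GEA6 (AT2G40170) fell to 37.0 FPKM from 1292, CRA1 (AT5G44120) to 81.1 FPKM from 2143, OLEO4 (AT3G27660) to 5.57 FPKM from 180.2 and the albumin gene SESA3 (AT4G27160) to 1.30 FPKM from 71.0, with q from 0.00125 to 0.0407 in the authors' deposited table. Expansins and xyloglucan enzymes gave 9 of 18, 7 higher and 2 lower (Fisher adjusted p = 0.816), and suberin genes 5 of 9, all higher (0.893), without passing for direction among all called loci (0.186 and 0.119). At a change of at least 2-fold, 6 expansin and xyloglucan genes were higher and 0 lower (Fisher adjusted p of direction = 0.0177), and 5 suberin genes were higher and 0 lower (0.0423). The other largest falls in the authors' deposited table were those of AT2G38905, 79.4-fold, the oil body gene ATS1 (AT4G26740), 74.5-fold, and the heat shock gene ATHSP22.0 (AT4G10250), 59.3-fold. MIR157a (AT1G66783) fell 52.3-fold and the glycine-rich protein gene AT2G05580 50.2-fold in the authors' deposited table. Among rises in the authors' deposited table the largest were those of AT5G44400, 46.0-fold, GLP6 (AT5G39100), 19.3-fold, and AGL42 (AT5G62165), 16.5-fold to 38.4 FPKM. SP1L2 (AT1G69230), of the SPIRAL1 microtubule family, rose 13.9-fold, the chitinase gene AT2G43590 11.8-fold and PLP6 (AT2G39220) 11.1-fold in the authors' deposited table.

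Of the 1777 loci called, 700 were higher and 1077 lower, and at least 2-fold 277 and 593. The seed reserve call ended at a q under 0.01 (Fisher adjusted p = 0.168) and at a change of at least 2-fold (Fisher adjusted p = 0.377).

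Age calls were shared between environments and genotypes beyond independent lists, in sku5 between environments by the least. WS shared 476 age calls between ground and spaceflight, against 243 for independent lists, with 472 in the same direction. In sku5 423 were shared, against 371 for independent lists, with 410 in the same direction. The 219 loci higher at 8 d in both environments in WS compare with 49.4 for independent lists (Fisher adjusted p = 1.05e-103), and the 209 in sku5 with 73.7 (Fisher adjusted p = 2.21e-55). On the ground the genotypes shared 428 age calls, 422 in the same direction, and in spaceflight 485, 470 in the same direction. The age effect differed between spaceflight and ground for 4 of 456 loci tested in WS and for 7 of 423 in sku5, computed here in the same way from the authors' deposited tables. In WS the defensin-like gene AT5G33355 fell by 3.84 on the log2 scale on the ground and by 0.99 in spaceflight (difference 2.85, standard error 0.62). In sku5 AT1G19530 rose by 2.13 on the ground and fell by 2.64 in spaceflight (difference -4.78, standard error 0.84), and the catalase gene CAT3 (AT1G20620) rose by 0.91 on the ground and fell by 0.93 in spaceflight (difference -1.84, standard error 0.52).

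The mutant was set against WS to ask which root transcripts differ with the sku5 mutation. At 4 d on the ground, the iron uptake and homeostasis list passed, with higher levels in sku5, and late embryogenesis and storage genes were among the largest falls. Of 9 iron genes, 5 were called and all were higher in sku5 (Fisher adjusted p = 0.0203, and 0.186 for direction). The age comparison of sku5 on the ground, where the iron list also passed, holds the same sku5 ground libraries of 4 d. The AT4G19650 and IRT1 locus stood at 336 against 152 FPKM (q = 0.00966), bHLH38 and bHLH39 at 133 against 53.9 FPKM, CYP82C4 (AT4G31940) at 34.7 against 11.9 FPKM and the ferritin gene FER1 (AT5G01600) at 272 against 121 FPKM (q = 0.0403) in the authors' deposited table. Seed reserve genes gave 3 of 9, all lower, and did not pass (Fisher adjusted p = 0.266, and 0.437 for direction). The largest falls in the authors' deposited table were all of loci higher in sku5 in spaceflight than on the ground at the same age, in comparisons that share the sku5 ground libraries: AT1G54870 at 0.530 against 118 FPKM, GEA6 (AT2G40170) at 2.08 against 195 FPKM and the late embryogenesis gene AT3G17520 at 0.873 against 58.6 FPKM. PAP85 (AT3G22640) stood at 0.831 against 53.2 FPKM, the late embryogenesis gene AT3G15670 at 0.687 against 29.4 FPKM, and AT1G03106 at 4.73 against 191 FPKM, in the authors' deposited table. The largest rises in the authors' deposited table were those of RNS1 (AT2G02990), 4.88-fold (q = 0.0189), the glucosidase gene BGLU34 (AT1G47600), 4.26-fold, and AT1G73120, 3.53-fold. AT1G65500 was 3.31-fold higher, the oxygenase gene AT5G43450 2.98-fold and AT2G41730 2.95-fold in the authors' deposited table.

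Of the 381 loci called, 183 were higher in sku5 and 198 lower, at least 2-fold 65 and 91, and 13 are listed at 0 in sku5. The iron call ended at a change of at least 2-fold (Fisher adjusted p = 0.113).

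At 8 d on the ground, nitrate, hypoxia, suberin and auxin genes called in the genotype comparison were all higher in sku5. None of the gene lists passed its test here, so the 4 lists with most called members are described. Auxin genes tied at 3 called members with expansins and xyloglucan enzymes and with touch and calcium genes, all higher. They were taken by the order of list names. Nitrate and ammonium genes gave 5 of 11 loci, with NRT1.1 counted at both of its loci (Fisher adjusted p = 0.0696), and hypoxia genes gave 4 of 10 (Fisher adjusted p = 0.173). Both loci given to the nitrate transporter NRT1.1 (AT1G12110) were higher, at 39.7 against 25.6 FPKM and 54.5 against 27.1 FPKM, as were nitrate reductase NIA1 (AT1G77760) at 29.0 against 16.4 FPKM and the merged locus GLT1, ACBP1 and AT5G53480 (AT5G53460) at 225 against 138 FPKM in the authors' deposited table. The hypoxia genes FTM1 (AT1G43800) at 16.2 against 4.19 FPKM, HB1 (AT2G16060) at 177 against 91.7 FPKM, SUS4 (AT3G43190) at 5.12 against 2.68 FPKM and LBD41 (AT3G02550) at 18.7 against 12 FPKM were higher in the authors' deposited table. Suberin genes gave 4 of 9: in the authors' deposited table CASP1 (AT2G36100), of the Casparian strip, stood 1.63-fold higher, CASP4 (AT5G06200) 1.66-fold, the FAR5 and FAR8 locus 1.65-fold and CYP86A1 (AT5G58860) 1.68-fold. Auxin genes gave 3 of 20: DFL1 (AT5G54510), which conjugates auxin, at 7.96 against 4.33 FPKM, ARF19 (AT1G19220) at 3.79 against 2.17 FPKM and IAA7 (AT3G23050) at 51.3 against 36.8 FPKM in the authors' deposited table.

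Largest among the rises in the authors' deposited table were those of AT2G01008, 6.68-fold, AT1G73490, 5.98-fold, and AT1G12805, 5.06-fold. The IRT1 locus was 4.92-fold higher (q = 0.00381), EARLI1 (AT4G12480) 4.85-fold and AT5G19890 4.65-fold in the authors' deposited table. Largest among the falls in the authors' deposited table were those of the LPP2 and AT1G15090 locus (AT1G15080), 17.9-fold, MIR158b (AT1G55591), 14.9-fold, and the kinase gene BSK10 (AT5G01060), 5.43-fold. AT4G13575 was 4.76-fold lower, a locus of chromosome 4 without a gene name 4.34-fold and OHP (AT5G02120) 4.05-fold in the authors' deposited table.

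Of the 525 loci called, 318 were higher in sku5 and 207 lower, and at least 2-fold 61 and 13. The loci that were lower had a median transcript length of 944.5 nucleotides, against 2033 for those that were higher.

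In spaceflight at 8 d, all 5 listed loci of the SKU5 family were called, SKU5 itself lower and the other 4 higher (Fisher adjusted p = 0.0455, and 0.344 for direction). The call rests in part on SKU5, whose level differs with the mutation, and without it the 4 relatives did not pass (Fisher adjusted p = 0.103), a test chosen after the data were seen. SKS6 (AT1G41830) stood at 80.9 against 50.2 FPKM (q = 0.00182), SKS1 (AT4G25240) at 11 against 7.0 FPKM (q = 0.0167) and sks17 (AT5G66920) at 82.1 against 56.8 FPKM (q = 0.0307) in the authors' deposited table. Class III peroxidases gave 6 of 17, all higher in sku5, without passing either list test. The largest rises in the authors' deposited table were those of AT1G03106 at 79.3 against 3.85 FPKM, the late embryogenesis gene LEA18 (AT2G35300) at 16 against 1.13 FPKM and AT2G21820 at 47.2 against 3.67 FPKM. The dehydrin gene XERO1 (AT3G50980) was higher by 3.34 on the log2 scale, AT5G44286 7.36-fold and GLYI8 (AT2G28420) 5.80-fold in the authors' deposited table. Among falls in the authors' deposited table the largest were those of AT1G12805, 16.3-fold, AT2G14247, 7.80-fold, and MIR160b (AT4G17788), 7.39-fold. The cytosolic invertase gene CINV1 (AT1G35580) was 5.83-fold lower, MIR161 (AT1G48267) 5.22-fold and the defensin-like gene AT5G33355 5.15-fold in the authors' deposited table.

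Of the 1409 loci called, 580 were higher in sku5 and 829 lower, with a median transcript length of 2306 and 903 nucleotides, and at least 2-fold 58 and 81. The SKU5 family call ended with a floor of 5 FPKM (Fisher adjusted p = 0.0508), at a q under 0.01 (0.29) and at a change of at least 2-fold (0.922).

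Genotype calls at 8 d were shared by 156 loci between ground and spaceflight, 120 of them in the same direction and 36 in opposite directions. The 89 loci lower in sku5 in both compare with 35.2 for independent lists (Fisher adjusted p = 3.33e-19), and the 31 higher in both with 37.8 (Fisher adjusted p = 0.262). The lean of lower loci to short transcripts, 1.11 on the ground and 1.35 in spaceflight in median log2 length, is not taken into account there either. The background of called loci sets the expected numbers high there too, so the shared rises do not show a lack of sharing. On the ground, 4 d and 8 d shared 52 genotype calls, 46 in the same direction. The 29 higher in both compare with 11.9 for independent lists (Fisher adjusted p = 6.43e-06) and the 17 lower in both with 8.4 (Fisher adjusted p = 0.00649).

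The gene lists that passed their test in none of the 11 comparisons are given by the comparison with their smallest p. Class III peroxidases had 9 of 17 members called for age in sku5 on the ground (Fisher adjusted p = 0.0685), nitrate and ammonium genes 5 of 11, NRT1.1 counted at both loci, for genotype on the ground at 8 d (0.0696), and auxin genes 9 of 20 for spaceflight in WS at 8 d (0.085). Cytokinin genes had 5 of 8 called for age in WS in spaceflight (0.173) and heat shock genes 6 of 12 for spaceflight in sku5 at 4 d (0.229). Root skewing genes had 2 of 4 for genotype on the ground at 4 d and touch and calcium genes 3 of 7 for genotype on the ground at 8 d (0.271 each). Flavonoid genes, of which 3 of the 14 fixed are listed, had 3 of 3 for spaceflight in sku5 at 8 d (0.295), root stem cell niche genes 2 of 2 for age in WS on the ground (0.353) and secondary wall genes 4 of 9 for age in sku5 on the ground (0.517). Clock genes had 0 of 10 (0.637) and root hair genes 0 of 8 (0.815) for age in WS in spaceflight. Defence genes had 2 of 6 (0.893), jasmonate genes 1 of 2 (0.947) and cell cycle genes 1 of 2 (0.947) for spaceflight in WS at 8 d. Cold and dehydration genes had 1 of 17 for spaceflight in WS at 4 d and light signalling genes 0 of 6 for age in sku5 on the ground (0.975 each). No gene of the chloroplast or mitochondrial genome is listed by name.

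**Figure D4:**
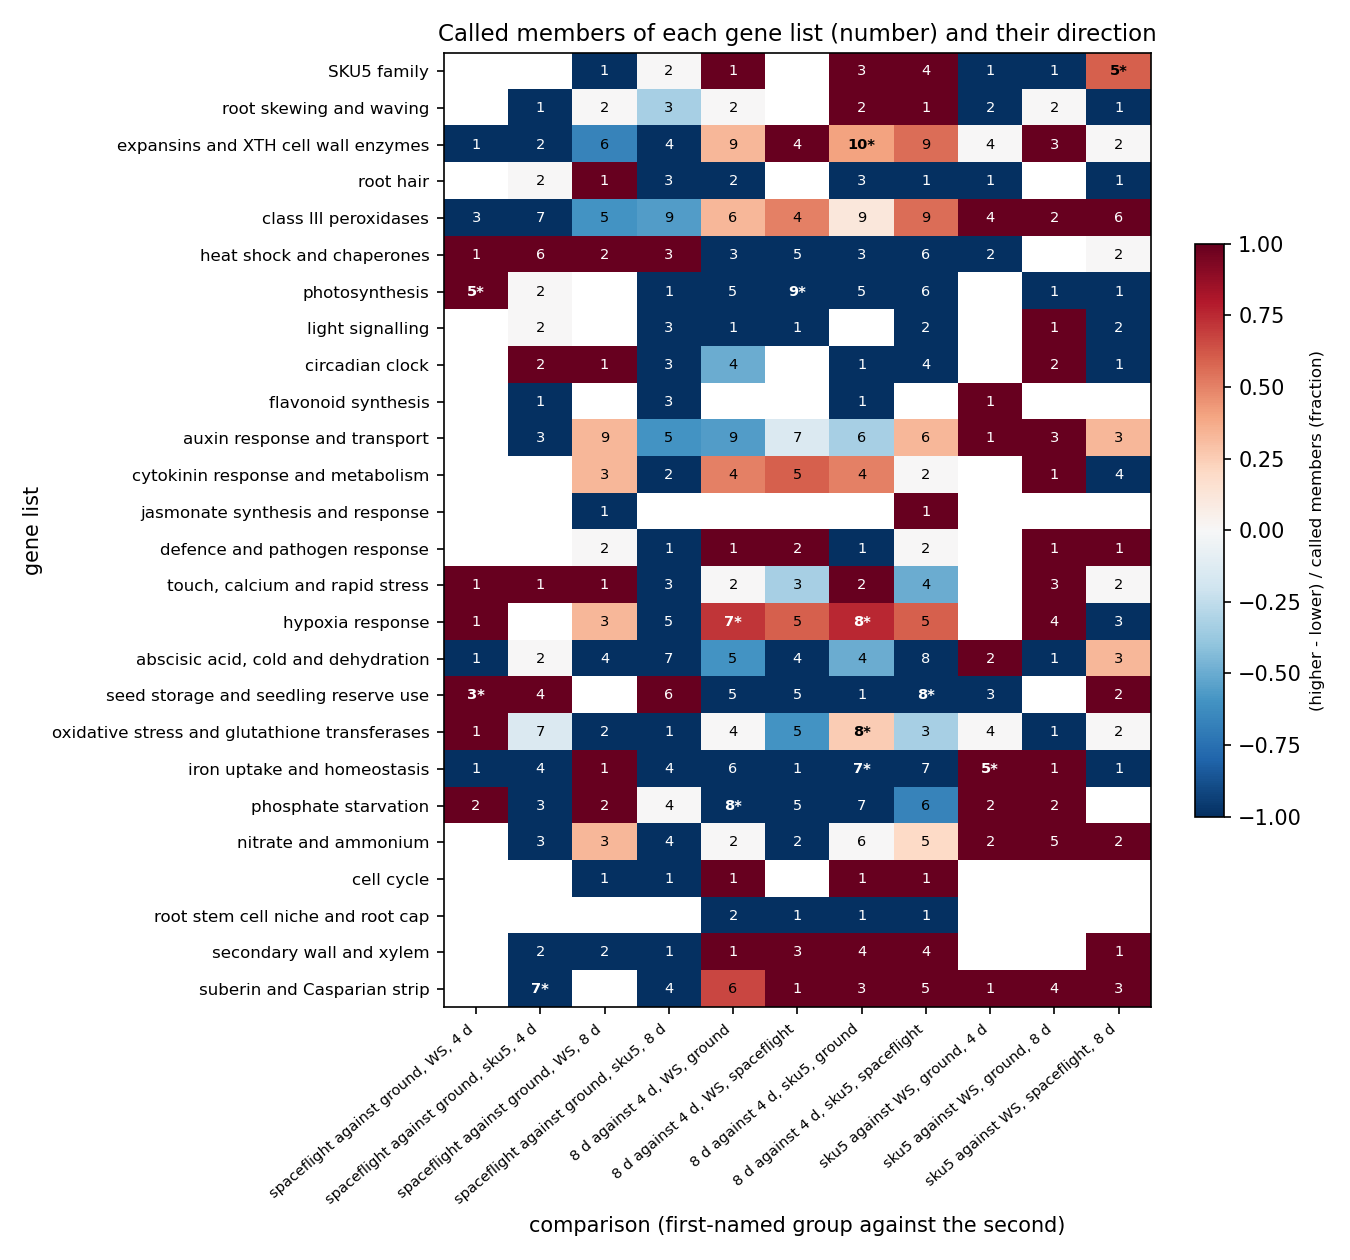
Each cell gives the number of members of a gene list called in a comparison, with a star where the list passed its over-representation test, and the colour gives the called members higher less those lower as a share of all called. The photosynthesis list is all higher for spaceflight in WS at 4 d, 5 members, and all lower with age in WS in spaceflight, 9 members, and both comparisons hold the same WS spaceflight libraries of 4 d.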

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

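Among the tests of this part, those of the mixing of RNA from a single source and of the comparison group were chosen after the result was seen, and those of developmental stage, transcript length, abundance and ribosomal protein genes before.

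At 4 d the spaceflight effect differed between sku5 and WS for 11 loci, and the differences, sku5 less WS on the log2 scale, were 9.58 for AT1G54870, 7.95 for GEA6 (AT2G40170), 6.92 for AT1G03106, 6.13 for AT2G21820, 4.91 for TSPO (AT2G47770), 3.78 for AT1G19530, 3.58 for MLS (AT5G03860), 3.12 for AT1G58235, 1.67 for EBP (AT3G16770), -2.93 for AT1G65500 and -4.33 for RNS1 (AT2G02990). At 8 d it differed for 12 loci, by -6.37 for AT1G12805, -4.12 for FTM1 (AT1G43800), -2.91 for AT5G33355, -2.77 for EARLI1 (AT4G12480), -1.24 for AT3G56290, -1.21 for AGP3 (AT4G40090), -1.18 for AT3G03270, -1.15 for AT2G46490, -1.05 for AT1G19960, -1.01 for AT2G18162, -0.90 for AT5G21020 and 0.94 for EIF4A-III (AT3G19760).

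The age effect differed between spaceflight and ground in WS, spaceflight less ground, by 2.90 for AT1G34047, 2.85 for AT5G33355, -1.49 for AT5G38020 and -6.82 for MIR158b (AT1G55591). In sku5 it differed by -4.79 for AT1G13340, -4.78 for AT1G19530, -3.06 for the merged locus ENGase85B and FER2 (AT3G11040, AT3G11050), -2.45 for ATM1 (AT3G19960), -2.28 for VAMP724 (AT4G15780), -1.89 for MLP328 (AT2G01520) and -1.84 for CAT3 (AT1G20620).

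In sku5 at 4 d, 42 loci taken by size alone were higher in spaceflight by at least 4 on the log2 scale, among them seed genes such as GEA6 and PAP85 (AT3G22640) but also MAF5 (AT5G65080) and NHX3 (AT5G55470), and 39 others are listed at 0 on the ground, while the seed reserve list did not pass its test (Fisher adjusted p = 0.507). Low levels in the sku5 ground libraries are argued against as the whole cause: 23 of 23 listed members were lower in sku5 than in WS on the ground (median log2 -3.12), yet the median log2 of sku5 spaceflight over WS ground, across separately scaled tables, was 2.65. RNA of a single source such as seeds, mixed in at unequal share, may be part of the cause. The log2 of sku5 spaceflight over WS ground had a standard deviation of 0.15 over 30 members against 0.75 over 94 other risen loci (permutation p = 1e-04, the smallest they can give). Other ratios were less uniform. The standard deviation was 0.375 over 20 members for sku5 spaceflight over WS spaceflight at 4 d. For 8 d over 4 d in sku5 in spaceflight it was 0.64 over 36 members, against 0.97 over 258 other risen loci. As 12 of the 42 members also have no listed WS ground level, a single source stays open for the whole set. Under an earlier stage of the seedlings, loci lower in sku5 in spaceflight should rise with age in WS on the ground more often than other loci. The odds ratio for that was 0.799 (Fisher's exact test, p = 0.303), an outcome set before as counting against an earlier stage. At that p the odds ratio is too uncertain to decide, so an earlier stage cannot be told apart either. Slow or failed germination of some seeds in either sku5 group stays open as a biological source and was not tested.

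In sku5 in spaceflight at 8 d the loci that were lower had shorter transcripts, with medians of 1009 against 2286 nucleotides, and higher FPKM, 115 against 22, than those that were higher. Ribosomal protein genes alone are argued against, since without them the difference of median log2 length was 1.15, or 97.6% of its value. A length bias of the libraries is a candidate explanation, as the difference was at least 0.86 within each of 5 strata of abundance. Abundance-dependent scaling cannot be told apart, since the difference of median log2 FPKM within 5 strata of length ran from -0.43 to 3.32. The difference of median log2 length was also 1.11 for sku5 against WS on the ground at 8 d and 0.89 for spaceflight in WS at 8 d, so it is not particular to spaceflight, and a biological source was not tested.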

How the results depend on the processing

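The single-gene loci, the sku5 spaceflight comparison at 4 d without loci listed for genotype on the ground, and the SKU5 family without SKU5, were chosen after the data were seen. No paired analysis was possible because the tables hold no values per library, and for the same reason the pseudocounts, the replicate block and the repeats without each replicate were not run. Depth is unknown, so what it limits was not tested. Of 391 alternatives, 307 kept the side of the threshold or, for counts, the size, 84 did not, and no tested effect reversed. Some could hardly change: all 39 calls tried with all reference genes as background stayed, and a wider background favours them. Counts of loci and direction tests could not be found reversed by the way they were labelled. The larger side of the calls turned in 7, from lower to higher: for spaceflight in WS at 4 d from 63 higher and 65 lower to 52 and 29 at a log2 change of at least 1, 13 and 1 at 2, and 62 and 53 for single-gene loci. In WS at 8 d it went from 410 and 478 to 88 and 55 at 1 and 12 and 5 at 2. At 2 it also went from 540 and 1108 to 16 and 15 for spaceflight in sku5 at 8 d, and from 580 and 829 to 17 and 16 for genotype in spaceflight. Fewer loci remain by construction under the stricter limits. A q under 0.01 leaves no locus for spaceflight in WS at 4 d, and 576, 452 and 1017 for spaceflight in sku5 at 4 d, WS at 8 d and sku5 at 8 d. It leaves 594, 582, 588 and 1029 for age in WS ground, WS spaceflight, sku5 ground and sku5 spaceflight, and 186, 284 and 772 for genotype on the ground at 4 d, at 8 d and in spaceflight. In that order, from WS at 4 d on, an absolute log2 fold change of at least 1 leaves 81, 634, 143, 243, 508, 440, 486, 870, 156, 74 and 139 loci, and of at least 2 leaves 14, 199, 17, 31, 138, 128, 103, 287, 37, 16 and 33. Against 13 list calls, 7 pass at a q under 0.01, 4 at a log2 change of at least 1, and 94 with all reference genes as background. Direction calls go from 0 to 4 at a log2 change of at least 1, and the cause was not tested. Of the 26 overlap calls, 12 alternatives lost the call, 5 of them because no locus of WS at 4 d is left at a q under 0.01. The call of a difference for AT3G56290 ended at log2 of the values plus 1, where the difference was -1.21.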

Other observations

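Tests of an oxygen-related response, with its gene list, and of the ribosomal protein genes were chosen after the result was seen. That of the general lean of the table was chosen before, but it used the gene list chosen after.

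Genes for ribosomal proteins, the protein part of the translation machinery, leaned to lower levels in several comparisons. With age in WS in spaceflight all 75 called were lower, against 50.7 for loci in the same broad class of length and abundance (adjusted permutation p = 6e-04). Differences of length and abundance within a class were not taken out, and the permutation treated the genes as independent. These p-values therefore cannot set ribosomal protein genes apart from the general lean. For age in WS in spaceflight that lean was hardly one of length, with median transcripts of 1429 nucleotides for loci higher and 1404 for loci lower. Loci lower there had higher FPKM, with medians of 48.2 against 29.0. In sku5 against WS at 8 d, 31 of 32 were lower on the ground against 24 (adjusted permutation p = 0.0012), and 97 of 97 in spaceflight against 92.7 (adjusted permutation p = 0.0188). With age in sku5 in spaceflight 24 of 24 were lower, against 21.1 (adjusted permutation p = 0.136), and for spaceflight in sku5 at 8 d 44 of 47, against 44.6 (adjusted permutation p = 0.762). With age in WS on the ground 5 of 11 were lower (adjusted permutation p = 1.0).

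Hypoxia genes, from a list of 31 genes of which 16 were also in the list fixed before, gave 7 higher of 7 called in sku5 against WS on the ground at 8 d, and 1 higher and 5 lower in spaceflight, and neither direction passed (Fisher's exact test, adjusted p = 0.168 and 0.501). The general lean of the spaceflight table by length and abundance cannot be told apart for the falls, as the permutation p within strata was 0.601, while for the rises on the ground it was 0.0048. The list and the pattern were chosen after those rises were seen. The p of 0.0048 therefore restates the choice and cannot set the rises apart from the lean. An oxygen-related response that differs between the genotypes with spaceflight cannot be told apart either: the directions differed between the tables (Fisher's exact test, p = 0.00466), but that only restates the pattern, and other loci leaned apart as well, 311 higher and 207 lower on the ground against 579 and 824. In the authors' deposited tables the hemoglobin gene HB1 (AT2G16060) stood at 177 against 91.7 FPKM on the ground and 80.8 against 113 FPKM in spaceflight, and FTM1 (AT1G43800) at 16.2 against 4.19 and 5.04 against 22.8 FPKM. No oxygen level is given in the sources used here, so the source of the difference stays open.

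The direction of that list passed in 1 of the 11 comparisons, age in sku5 on the ground, where 12 of 12 called members rose (Fisher's exact test, adjusted p of direction = 0.00506). The hypoxia list fixed before gave 7 higher and 1 lower for age in sku5 on the ground. It did not pass for direction (Fisher's exact test, adjusted p = 0.235). The member of the fixed list that fell is not in the list chosen after the result was seen. This age comparison also holds the older sku5 ground libraries of the genotype comparison in which the rises were first seen. The passing direction therefore restates those choices in part, and no conclusion is drawn from it.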
